A study of Mus musculus with 19 samples.

How the data were processed

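The 19 mouse samples cover 4 kinds of measurement of the methyl-CG binding protein MECP2 and of its surroundings in brain. Chromatin immunoprecipitation with an antibody from Sigma (ChIP, which recovers DNA bound by a protein) was sequenced with a matching input in 4 preparations: sonicated whole brain, and chromatin digested with micrococcal nuclease (MNase) into mononucleosomes of whole brain, mononucleosomes of cerebellum and dinucleosomes of cerebellum, each with 1 MECP2 library and 1 input library from male wild type tissue. RNA-seq was made from 1 Mecp2 null and 2 wild type cerebellum samples, with different strain labels. RNA immunoprecipitation (RIP, which recovers RNA bound by or close to a protein) with the MECP2 antibody was made from 3 male and 3 female cerebellum samples, with no control precipitation among the labels. Methylated cerebellar DNA was captured with MethylMiner, a kit that binds DNA to a methyl-CG binding domain, in 1 fraction of low and 1 fraction of high methylation. The label of the low fraction also lists the MECP2 antibody, which this capture does not use. It was taken as titled, and the doubt bears on every ratio of high to low density. Samples were grouped by assay, tissue, preparation, genotype and sex as labelled. Nothing in the labels says that replicates are separate animals, so the p-values of sample comparisons measure only the spread between these samples.

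Per the submitters' processing notes, BWA 0.5.7 and the mm9 genome were used. The counting tool, the strandedness and the gene annotation are not given in the sources used here. All positions are mm9 positions from the deposited tables. Per the file headers, the RNA-seq and ChIP signal is a read count normalised for total reads. The deposited RNA-seq signal holds whole multiples of 1 step per library, from which whole reads were recovered. The ChIP signal deposited by the authors is a coverage summed over the bases within 1000 bp of each transcription start site (TSS), in units of bases, not reads. Wild type expression is deposited as RPKM, and both wild type columns were summed by the authors. The deposited RIP signal is in reads per 1000 bp of the gene's span from start to end, and multiplying by the span gave back whole reads. The authors' deposited table of RIP relative to expression is a ratio of that signal to the summed RPKM. The deposited methylation capture values are read counts per 2 kb TSS region without scaling. Other columns are the CG number and the CGAT4 number of each TSS region, which per the file headers count sequence, not reads; CGAT4 is not defined there. Another of the deposited tables lists TSS regions with at least 50 CG sites, in 4 classes by wild type activation or repression and by a CGAT4 number above 18 or below 7.

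The deposited fold change is the ratio of the null value to each wild type value. It differed from the ratio recomputed here by more than 0.001 for 7787 of 19965 entries in the first column (39.0%) and for 6457 of 20368 in the second (31.7%). In 100% of these the difference was explained by zeros missing from the decimals, and none of them (0 entries in each column) moved to the other side of 1. In the authors' deposited table Mecp2 stands at 0.163 and 0.184, where the libraries give 0.0163 and 0.0184, and Atp6v1h stands at 1.83 in the first column where they give 1.08. Ratios were therefore recomputed from the libraries. The gene tables hold 31481 entries with 31370 different symbols; 109 symbols stand on several entries, of which the transcript with the highest mean value was kept, and 27 symbols had been turned into dates.

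Male and female RIP libraries were compared with limma 3.58.1 (moderated, with a mean trend, two-sided) in R 4.3.3, on log2 of CPM of the recovered reads plus 0.5 (CPM being reads scaled to library size), with TMM library sizes and the filterByExpr filter of edgeR 4.0.16, and a Benjamini-Hochberg adjusted p under 0.05. The table of 69 long non-coding RNAs (lncRNAs) was tested the same way with library sizes from the gene table. Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated one. Recovered reads rather than deposited reads per 1000 bp were used because the span is the same in every library. On simulated data with 200 changed genes the limma test found 47% of 2-fold and 93% of 4-fold changes with 1 false call among 12873 genes. In this simulation and in that of the null test below, every gene had the same dispersion. Changes were placed only in genes with a mean of at least 20 reads. The shares found may therefore overstate what the tests find in the real data, where the spread differs between genes. The null library was compared with the wild type libraries mainly by description, as log2 of the scaled value plus 0.5 minus the wild type mean, among genes with at least 1 RPKM and with 1.5-fold as the threshold. The edgeR quasi-likelihood test was added on recovered reads with 1 residual degree of freedom, in which the lone null sample is assumed to vary like the wild type samples; on simulated data it found 46% of 2-fold and 99% of 4-fold changes with 10 false calls among 14038 genes.

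ChIP enrichment was log2 of bound over input, each plus 50 coverage units, for TSSs with at least 2000 units in bound plus input, which corresponds to 20 reads at 100 units per read. Methylation capture was log2 of high over low CPM, each plus 1, for TSSs with at least 20 reads. RIP relative to expression was the mean log2 CPM (plus 0.5) over the 6 RIP libraries minus that over the 2 wild type RNA-seq libraries. Both were taken from the same gene entry, for genes with at least 1 RPKM and a mean of at least 20 RIP reads. Whether RNA-seq reads were counted over the whole span or over exons alone is not given, so the RIP and RNA-seq counts may not be alike. RIP and RNA-seq libraries were made with different kits. Relations between assays are Spearman correlations across genes, which are not independent replicates, so they carry no p-value. Region classes were compared with two-sided permutation tests over regions (100000 resamples, 24 tests, Benjamini-Hochberg adjusted). Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used for the rest.

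The 25 gene lists were fixed before the data were examined, as were the comparisons, the rule for named genes and most alternatives. They are markers of granule neurons, Purkinje cells, inhibitory neurons, astrocytes with Bergmann glia, oligodendrocytes, microglia, endothelial with mural cells and choroid plexus, blood cell genes, genes reported as MECP2 targets, glucocorticoid-responsive, immediate early, imprinted, Y-linked, long neuronal, synaptic, oxidative phosphorylation, ribosomal protein, housekeeping, germline, Hox, olfactory with vomeronasal receptor and DNA methylation genes, lncRNAs, and X genes escaping inactivation. Outside the sex comparison a list's median was ranked among the medians of 10000 random lists of the same size, matched in 20 bins on expression (null and RIP) or input coverage (ChIP), and called outside when it lay below the 2.5 or above the 97.5 percentile. Such a rank describes these libraries and is no p-value.

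Genes were named by rule: in the sex comparison up to 10 per direction with the lowest p past the threshold, with the Y-linked list and Xist; in the null the 12 largest increases and 12 largest decreases with the null value outside both wild type values, Mecp2 first; in ChIP and methylation capture the 10 highest and 10 lowest TSSs; in RIP the 10 most abundant RNAs and the 10 highest and 10 lowest ratios; up to 20 lncRNAs with a mean of at least 20 reads; up to 4 members of a list with the largest values; and Mecp2 throughout. Predicted genes (Gm and Rik symbols) were counted but left unnamed where more than 3 per direction qualified. Small RNA genes were named in the ChIP and methylation tables.

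Intervals of low counts are 95% exact (Clopper-Pearson) intervals of the ratio of reads. A fold against a count of 0 used a floor of 3 counts over the group. Intervals and floors cover counting error only. Alternatives covered library scaling, filters, pseudocounts, tests, thresholds, matching, leaving out each replicate and, for the sex comparison, a replicate block. The replicate numbers do not pair male with female libraries, so no block was used in the values reported. DESeq2 1.42.0 served as another test. Pseudogene names were taken from RefSeq annotation of the GRCm38 assembly, used for names alone. The tool behind the deposited normalisation and reads outside the gene tables were not analysed here.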

Results

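MECP2 binding, DNA methylation and RNA were profiled in mouse brain with 19 samples. RNA-seq of cerebellum comprised 1 Mecp2 null library with 13821349 reads in genes and 2 wild type libraries with 14478203 and 16717470. The 3 male MECP2 RIP libraries held 2387637, 1737722 and 507104 reads in genes, and the 3 female ones 3472601, 694670 and 2088638. Their lncRNA table held 5389 to 30432 reads per library. The low and high methylation capture fractions held 210615 and 321457 reads at TSSs, of which the 10 most covered TSSs took 31.9% and 22.0%. Summed ChIP coverage, in megabases for input and MECP2, was 367 and 435 in sonicated whole brain and 82.3 and 131 in mononucleosomes of whole brain. It was 280 and 402 in mononucleosomes of cerebellum, and 465 and 833 in dinucleosomes of cerebellum. The 10 most covered regions took 24.1% to 68.5% of a ChIP library. ChIP, methylation capture and the null RNA each had 1 library per arm, so their differences have no replicate check apart from the pair of wild type RNA libraries.

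The RNA-seq comparison asked which RNAs differ in cerebellum without MECP2. The strain labels of null and wild type samples differ, so strain and genotype cannot be told apart here. Mecp2 itself (chromosome X, 71271931 to 71331029) stood at a scaled value of 115 in the null against 7064 and 6280 in wild type, a log2 change of -5.84, with 51 null reads left. Transcription factor genes induced by neuronal activity were lower too. Fos (chromosome 12, 86814840 to 86818223) stood at 220 against 1558 and 1463, and the nuclear receptor gene Nr4a1 (chromosome 15, 101097277 to 101105223) at 224 against 1121 and 1315. The neuronal factor Npas4 was at 15.8 against 170 and 103, with 7 null reads for 134 in wild type (ratio 0.118, interval 0.0465 to 0.25), and Egr4, a zinc finger factor of the same response, at 58.9 against 232 and 409. With edgeR, 3 of 14038 genes passed, and all 3 fell: Mecp2 (log2 -5.78, adjusted p = 0.000343), Fos (-2.71, adjusted p = 0.0185) and Nr4a1 (-2.37, adjusted p = 0.0468); 1154 genes had an unadjusted p under 0.05.

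Among genes higher in the null library, Zbtb16, a transcription factor gene induced by glucocorticoids, was at 620 against 136 and 198 (log2 1.92, edgeR adjusted p = 0.241). Fstl4, which encodes a follistatin-like secreted protein, was at 1243 against 577 and 557, and Fxyd6, a regulator of the sodium pump, at 5155 against 2568 and 2708. Other higher genes were the glucose transporter gene Slc2a4 (log2 1.21), the cytokine receptor gene Il31ra (1.21), the mitochondrial leucyl-tRNA synthetase gene Lars2 (1.03), and the DNA repair gene Xrcc2 (0.98). They also included the AMPA receptor partner Gsg1l (0.93), the semaphorin receptor gene Nrp2 (0.90), the synaptic adhesion gene Lrrtm4 (0.88), Myoc (0.86) and Sspn (0.85). For Myoc the wild types themselves differed by -1.25, more than the change. Lower genes included Crym, which encodes a thyroid hormone binding protein, with 1 null read against 222 and 36 in wild type (ratio 0.00875, interval 0.000221 to 0.0492), a gene whose wild type libraries themselves differed by 2.82 on the log2 scale. Adm2, a peptide hormone gene, had 1 null read for 37 (0.061, 0.0015 to 0.362), and Ifi27l2a, an interferon-induced gene, 2 for 33 (0.137, 0.0159 to 0.535), where the wild types differed by -2.59. The rest were the phosphatase gene Ppm1j (log2 -2.78), the potassium channel gene Kcna3 (-2.72, with -1.97 between wild types), Kbtbd8 (-2.44), the neuropeptide gene Nmb (-2.28) and Mdfi (-2.27).

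In all, 107 genes were at least 1.5-fold higher and 1585 at least 1.5-fold lower in the null library than the wild type mean, of which 31 and 387 were predicted genes and 8 and 23 small RNA genes. The 2 wild type libraries differed from each other about as much, with 274 genes higher and 1261 lower in the first, and the SD of log2 differences was 0.39 for null against wild type and 0.41 between wild types. The null change and the difference between wild types correlated at 0.45 across genes. Genes lower in the null thus tended to be lower in the first wild type library than in the second. Counts moved with the wild type library used: 1273 genes without the second (196 higher), and 2737 without the first (259 higher). Without the filter 2837 of 5946 genes were higher. The share of higher genes among the 1692 against the wild type mean was 6.32%, 11.9% after centring on the median gene (-0.07), and 33.9% in the authors' deposited table of fold changes, where missing zeros enlarge ratios just above 1, such as 1.83 for 1.08 at Atp6v1h.

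**Figure D1:**
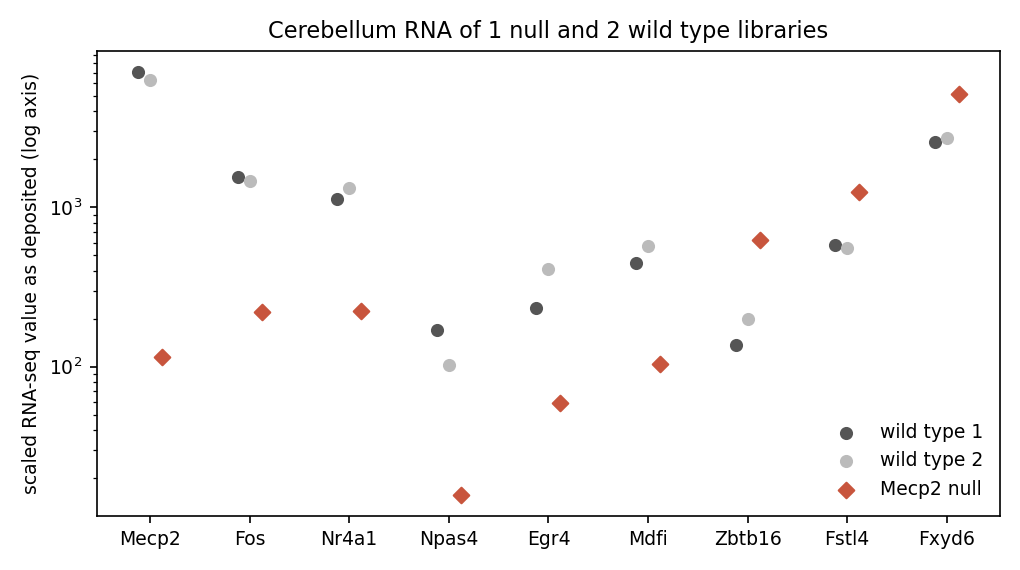
Scaled RNA-seq values as deposited (log axis) of 9 genes in 1 Mecp2 null and 2 wild type cerebellum libraries, 1 point per library. Mecp2 and 5 lower genes (Fos, Nr4a1, Npas4, Egr4 and Mdfi) lie below both wild type points, and Zbtb16, Fstl4 and Fxyd6 above both.

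The gene lists asked whether cell types or pathways moved together in the null cerebellum. Immediate early genes, which are transcribed within minutes of neuronal activity, stood apart: their median log2 change was -1.20, 10 of 14 members were at least 1.5-fold lower and none higher (0 of 14). Against the first and second wild type library alone the median was -1.03 and -1.21, while the wild types differed by -0.18. Markers of the main cerebellar cells lay close to 0, with granule neurons at 0.02, Purkinje cells at -0.07, astrocytes with Bergmann glia at -0.01 and oligodendrocytes at -0.02. Within them Rora, a nuclear receptor gene needed by Purkinje cells, was at -0.98 and Fabp7, a fatty acid binding protein of Bergmann glia, at -1.71. Genes reported as MECP2 targets went both ways, with 3 higher and 4 lower of 24. Lower were the neurotrophin gene Bdnf at 177 against 476 and 536 (-1.51), Creb1 at -1.33, Igfbp3 at -1.0 and the ubiquitin ligase gene Ube3a at -0.92. Higher, and named here after their values were seen, were Fkbp5 (0.68), Reln (0.61) and Irak1 (0.59). For Ube3a and Reln the wild types differed by more than the change (-0.98 and 0.64). DNA methylation genes had a median of -0.22, with the methylcytosine oxidases Tet2 at -1.22 and Tet1 at -0.77 and the methyl-CG binding protein gene Zbtb33 at -0.80. This list holds Mecp2 itself, and without it lay inside the random range (percentile 3.1).

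Of 24 lists, 8 lay outside the middle 95% of random lists matched on expression. Besides immediate early genes and the DNA methylation list with Mecp2 these were lncRNAs (-0.50, with Tug1 at -1.17 and Gas5 at -0.67), ribosomal protein genes (-0.09), long neuronal genes (0.08), inhibitory neuron markers (0.15), housekeeping genes (0.15) and glucocorticoid-responsive genes (0.23, with Fkbp5 at 0.68 and Tsc22d3 at 0.55). The glucocorticoid list changed side with the wild type library, at -0.05 against the first and 0.60 against the second, and lncRNAs ranged from -0.14 to -0.70. Against the same libraries housekeeping genes were at 0.05 and 0.23, ribosomal protein genes at -0.19 and 0.01, and DNA methylation genes at -0.10 and -0.27. Inhibitory neuron markers were at 0.09 and 0.04, and long neuronal genes at 0.13 and 0.04. Some calls ended under other settings: at 5 RPKM the DNA methylation, inhibitory neuron and long neuronal lists were inside (percentiles 26.8, 96.5 and 90.6), and without matching the ribosomal protein and DNA methylation lists were (34.5 and 4.15). Markers of other cells were inside, with microglia at -0.24 (0.01 against the first wild type and -0.48 against the second, and outside at 5 RPKM with -0.45), endothelial and mural cells at -0.08, blood at -0.04 and choroid plexus at 0.03, although the choroid plexus transporter gene Ttr had 44 reads in the null, 47 in the first wild type and 0 in the second.

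MECP2 ChIP at TSSs asked where MECP2 sits and on what sequence. In cerebellar dinucleosomes, promoters rich in CG sites held more MECP2 over input than promoters poor in them: TSSs with 91 to 311 CG sites had a median log2 of 0.54 and those with 0 to 20 sites -0.38. Cerebellar mononucleosomes went the same way with a smaller range, from 0.16 to -0.19. Sonicated whole brain went the other way, with -1.17 at the CG-richest and -0.01 at the CG-poorest TSSs, and mononucleosomes of whole brain showed little trend, with -0.15 and -0.10. Across 30818, 27468, 31178 and 31139 usable TSSs the Spearman correlation with the CG number was -0.51 in sonicated whole brain, -0.03 and 0.25 in mononucleosomes of whole brain and cerebellum, and 0.50 in dinucleosomes. The median over all TSSs was -0.48, -0.11, 0.03 and 0.18 in the same order.

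**Figure D2:**
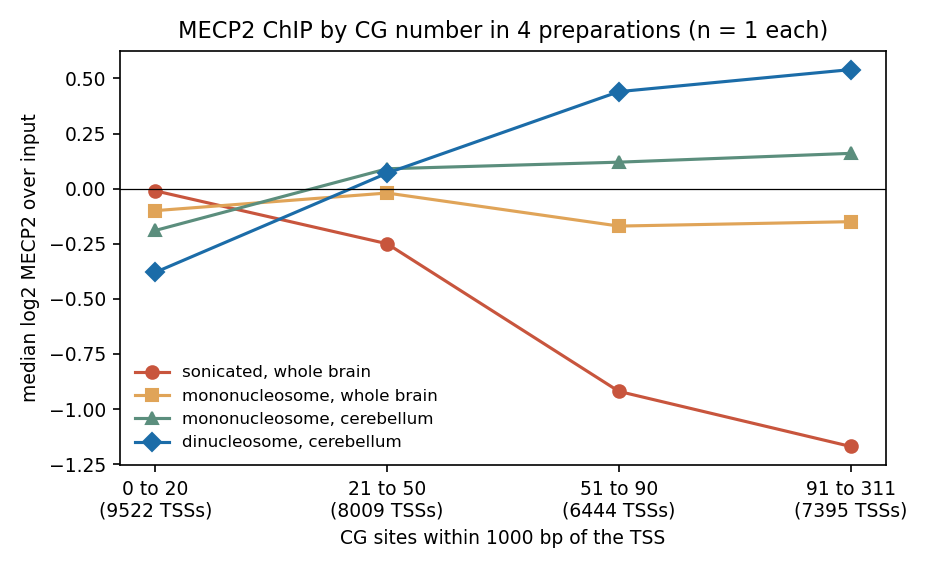
Median log2 of MECP2 over input in 4 classes of TSS by the number of CG sites within 1000 bp, 1 line per ChIP preparation (n = 1 each). The lines start between -0.38 and -0.01 at CG-poor TSSs and end at -1.17 for sonicated whole brain and at 0.54 for cerebellar dinucleosomes.

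The TSSs with the highest mean over both cerebellar preparations included promoters of expressed genes: Atp6v1a, a subunit of the vacuolar proton pump (chromosome 16, 44138818 to 44140818; mean log2 1.81), the transcription factor genes Pou2f1 (1.66) and Ubp1 (1.65), and Kctd15 (1.61). Promoters without detected RNA or nearly so were there too, with Shbg, the gene of a sex hormone carrier, at 1.73, the cartilage gene Cilp at 1.70, the olfactory receptor gene Olfr1036 at 1.64, and the small RNA genes U6.59 (1.82), n-R5s18 (1.79) and SNORA17.122 (1.69). Of these, U6.59 owed its mean to dinucleosomes (3.64, with 0.00 in mononucleosomes) and SNORA17.122 mainly to mononucleosomes (2.97, with 0.42 in dinucleosomes). Several of the highest TSSs had low mononucleosome input, with 252 units at SNORA17.122, 597 at Atp6v1a, 631 at Kctd15, 756 at Olfr1036 and 953 at Pou2f1. Others had more, such as Cilp with 4152 and U6.59 with 4114. In sonicated whole brain the expressed genes named here were at -2.64 (Atp6v1a), -5.4 (Pou2f1), -2.59 (Ubp1) and -0.53 (Kctd15). At the lowest 5 TSSs no dinucleosome MECP2 coverage was found, against input coverages of 3612 at Cylc2, a sperm head gene, 4110 at Prh1, a salivary protein gene, 2477 at Vmn2r72-ps, 2640 at Olfr832 and 2189 at Csn1s2b, a milk casein gene. Of these, only Cylc2 was also low in mononucleosomes (-1.65). The other low ones were the bitter taste receptor gene Tas2r123 (-2.80), U6.922 (-2.70), U3.46 (-2.64), Olfr890 (-2.57) and Olfr291 (-2.45). U6.922 and U3.46 were low in dinucleosomes alone (-5.59 and -5.37) and at 0.20 and 0.08 in mononucleosomes. The Mecp2 promoter was at 0.32 in mononucleosomes and 0.01 in dinucleosomes. In both cerebellar preparations 198 TSSs were at least 2-fold higher and 275 at least 2-fold lower, so 41.9% were higher; centred on the median TSS the counts were 99 and 397, or 20%.

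By gene list, the mean MECP2 of both cerebellar preparations was highest at promoters of granule neuron markers, the main neurons of this tissue, with a median of 0.64 against 0.10 for all TSSs. It was highest in neither preparation alone: mononucleosomes were led by DNA methylation genes (0.53, granule neurons 0.37) and dinucleosomes by ribosomal protein genes (0.83, granule neurons 0.76). Examples were the synapse organiser Cbln3 (1.11) and the transcription factor genes Zic2 (0.98), Etv1 (0.88) and Neurod2 (0.84). Ribosomal protein genes (0.55, Rpl4 at 1.18), DNA methylation genes (0.54, Tet3 at 1.12), housekeeping genes (0.49, Ubc at 1.03), synaptic genes (0.43, Rab3a at 1.21 and Snap25 at 1.04) and germline genes (0.31, the germ cell RNA binding protein gene Dazl at 1.55) also lay above random lists matched on input. Below them lay olfactory and vomeronasal receptor genes (-0.51), inhibitory neuron markers (-0.42, with the glycine transporter gene Slc6a5 at -0.88), Hox genes (-0.29, Hoxb8 at -1.14) and endothelial and mural markers (-0.29, Slco1a4 at -1.21). Taken alone, mononucleosomes left granule neuron, synaptic, germline and endothelial lists inside the random range (percentiles 92.7, 84.9, 63.1 and 11.7), and dinucleosomes left DNA methylation and Hox genes inside (94.5 and 6.69). Most of these directions did not hold in sonicated whole brain, where all TSSs had a median of -0.48. The order turned round for DNA methylation (-1.57), housekeeping (-1.53), ribosomal protein (-1.11), synaptic (-1.09), olfactory receptor (0.15) and endothelial (0.21) lists. Granule neuron (-0.75) and inhibitory neuron (-0.30) lists also changed side in sonicated whole brain, but lay inside the random range (percentiles 20.1 and 81.0). There, germline genes stayed high (0.15) and Hox genes stayed below the median TSS (-0.64). In mononucleosomes of whole brain, with a median of -0.11, Hox genes (-0.60) and olfactory receptors (-0.18) were low as in cerebellum. Ribosomal protein (0.27), synaptic (0.11), germline (0.06), inhibitory neuron (-0.17) and endothelial (-0.29) lists also kept their side of the median. The granule neuron (-0.38), housekeeping (-0.24) and DNA methylation (-0.18) lists lay on the other side. Apart from Hox genes and olfactory receptors, none of these lists was outside the random range. All random lists were matched on input coverage and not on the CG number. Whether a list stood apart beyond its CG content was therefore not tested.

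The 15 other lists were inside the middle 95% in the cerebellar mean, which leaves 10 of 25 outside. Cell markers among them were at 0.01 for Purkinje cells, 0.14 for astrocytes, 0.19 for oligodendrocytes, -0.32 for microglia, 0.16 for blood and 0.09 for choroid plexus. Oxidative phosphorylation genes were at 0.34, lncRNAs at 0.29, immediate early genes at 0.28, Y-linked genes at 0.26, imprinted genes at 0.23, reported MECP2 targets at 0.17, glucocorticoid-responsive genes at 0.14, long neuronal genes at 0.02 and X genes escaping inactivation at 0.01. Single promoters stood out within these lists, such as Klf9, a glucocorticoid-induced factor, at 1.59 and the imprinted Snrpn at -2.04.

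Agreement between preparations asked whether the same promoters were enriched each time. The closest were mononucleosomes and dinucleosomes of cerebellum, with a correlation of 0.28 across 31043 TSSs and 0.18 given the CG number. Sonicated whole brain ran against cerebellar dinucleosomes (-0.38) and mononucleosomes (-0.16), at -0.17 and -0.04 given the CG number. Mononucleosomes of whole brain showed little relation to any other preparation, with 0.07 to those of cerebellum, 0.04 to dinucleosomes and 0.02 to sonicated whole brain.

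Methylation capture asked which promoters carry DNA methylation in wild type cerebellum. Germline genes and imprinted genes were the most captured groups. The median of the germline list was 107 reads, and 28 of 30 promoters had at least 20. They included the meiotic chromosome gene Sycp1 with 197 high and 9 low density reads and Fkbp6 with 196 and 24. Imprinted genes, methylated on 1 parental copy, had a median of 48 reads and 20 of 33 had at least 20. They included Zrsr1 (188 and 36), Gnas (145 and 20), Cdkn1c (142 and 7) and Peg3 (123 and 28). Hox, granule neuron and immediate early promoters had a median of 0 reads. Ribosomal protein genes had a median of 10 reads, with 14 of 55 promoters at 20 or more, such as Rps29 (44 and 4) and Rpl13 (41 and 4). Among all 31370 TSSs the median was 3 reads, 4628 had none and 4199 had at least 20.

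In density, the 10 promoters with the highest ratios included Rpl10a, with 32 reads against 0 (at least 6.99-fold higher), Rps8 and Pebp1 with 22 against 0 (at least 4.81-fold), and Polr2c, Tmed10 and Hnrnpa1 with 20 against 0 (at least 4.37-fold). Rpl28 and Alox12e had 33 against 1 (ratio 21.6, interval 3.62 to 880), the imprinted antisense RNA gene Airn 77 against 3 (16.8, 5.54 to 83.3), and the testis gene Rbmxl2 134 against 6 (log2 3.83). Counts of 0 leave the order among these 10 open. The lowest were small nucleolar RNA copies of the imprinted Snrpn cluster, with 4 high and 17 low reads at SNORD115.13, 4 and 16 at SNORD115.122, and 5 and 18 at SNORD116.9. Also low were promoters with few CG sites such as the cytokine genes Il9 (4 and 16) and Il17a (6 and 21), the apolipoprotein gene Apof (5 and 19), Adam7 and Mir342 (4 and 16 each), U6.489 (5 and 19) and SNORA17.412 (5 and 18). Mecp2 had 0 high and 1 low read, too few for a ratio. At 20 reads or more, 1139 TSSs were at least 2-fold higher in the high fraction and 400 in the low fraction (74.0% higher). After centring on the median of 0.33 they were 803 and 724, or 52.6% higher. The balance moved with the read minimum, with 1458 and 1392 at 10 reads and 647 and 21 at 50 reads. The density ratio of ribosomal protein (2.46), germline (2.05) and imprinted (1.68) promoters lay above random lists and that of olfactory receptors (-0.02) below, and the other lists with enough reads were inside. These random lists had the same size but were not matched on the CG number, with which the density ratio correlated at 0.3. Whether a list stood apart in density beyond its CG content was therefore not tested.

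Setting ChIP against methylation capture, expression and the null asked whether MECP2 at a promoter goes with its methylation or its RNA. More captured promoters held slightly more MECP2 in 3 preparations and slightly less in the fourth: the correlation was 0.23 in sonicated whole brain, 0.12 and 0.05 in mononucleosomes of whole brain and cerebellum, and -0.11 in cerebellar dinucleosomes. Promoters of highly expressed genes held more MECP2 in cerebellar dinucleosomes, with a median log2 of 0.59 in the most expressed class against -0.28 at genes without RNA (correlation 0.48), and in cerebellar mononucleosomes, with 0.19 against -0.12 (0.22). In sonicated whole brain they held less, with -1.09 against -0.06 (-0.45). Given the CG number these were 0.22, 0.07 and -0.16. Genes grouped by cerebellar mononucleosome MECP2 had a like share of null changes above 0, from 37.3% to 41.0% over 5 classes. Genes at least 1.5-fold lower went from 357 in the class with least MECP2 to 294 in that with most, and from 410 to 245 in classes by dinucleosome MECP2. Genes at least 1.5-fold higher were fewer in the class with most MECP2 too, with 29 against 20 and, by dinucleosome MECP2, 35 against 19. The drop was thus not confined to lower genes. The correlation with the null change was 0.04 in both cerebellar preparations, 0.01 in mononucleosomes of whole brain and 0.00 in sonicated whole brain. Captured methylation was lower at expressed genes, with a median of 4 reads at genes without RNA and 2 in the most expressed class (correlation -0.24, and -0.04 given the low density reads).

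RIP against expression asked which RNAs come down with MECP2. Within the gene table, leaving aside the separate lncRNA table, the most abundant RNAs were mainly those of very long neuronal genes: Kcnip4, a potassium channel partner, with 7676 ± 1210 CPM (SD, n = 6), the splicing factor gene Rbfox1 with 4535 ± 392, the nuclear envelope gene Syne1 with 4530 ± 501, the potassium channel gene Kcnd2 with 4446 ± 703, the adhesion gene Kirrel3 with 4251 ± 375. Rora followed with 4190 ± 398, Dpp6 with 4016 ± 571, Fgf14 with 3785 ± 633 and the presynaptic adhesion gene Nrxn1 with 3153 ± 263. Galnt2, whose entry spans 4435 kb, had 4549 ± 376 CPM but a log2 ratio to expression of -0.17. Its wild type level was 5085 CPM at 11.1 RPKM, where Kcnip4 had 120 CPM at 31.5 RPKM. How far the reads of this long entry come from Galnt2 itself is therefore uncertain. Relative to expression, the axon guidance gene Slit3 was highest at 6.35, then Kcnip4 (5.98), the potassium channel genes Kcnq1 (5.96) and Kcnq3 (5.32), Xkr6 (5.81) and Fgf14 (5.78). The Kcnq1 entry holds the lncRNA kcnq1ot1, whose 471 mean reads equal 94.4% of the 499 counted for Kcnq1, so which of them the reads come from is uncertain. Next came Il1rapl1 (5.74), the NMDA receptor gene Grin2a (5.62), the ubiquitin ligase gene Park2 (5.19) and the calcium channel gene Cacna1c (5.12). Among genes with a mean of at least 20 RIP reads, the lowest were Myo3a (-4.35, with an SD over libraries of 1.14), the translation factor gene Eef1a1 (-3.87) and the globin gene Hba-a1 (-3.81). Several genes of astrocytes were close to these, the glycolytic Aldoc (-3.79), Gpr37l1 (-3.78), Hopx (-3.73), the water channel gene Aqp4 (-3.71) and S100b (-3.70), with Purb (-3.76) and Arl6ip1 (-3.68). Genes with fewer RIP reads were left out of this order, and Hba-a1 (20.3 mean reads), Purb (21.0) and Hopx (21.3) stood near that limit. Myo3a had 2771 wild type CPM at 14.1 RPKM, so how far its reads come from this gene is uncertain. Mecp2 RNA was recovered below its expression, at -0.68.

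RIP and expression correlated at 0.56 across 9422 genes. The ratio was higher at genes with longer spans: its median was -1.06 for spans of 0.087 to 12.2 kb and 1.10 for spans of 95.5 to 4435 kb, and its correlation with span was 0.53 (0.47 within expression classes), while RNA-seq reads had 0.02. The authors' own measure divides RIP by the span and expression by a shorter length, and its correlation with span was -0.44. Directions by span therefore depend on which measure is used.

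Gene lists in RIP relative to expression set apart long neuronal genes, lncRNAs and short, strongly expressed genes. All 37 long neuronal genes lay above the median gene, with a list median of 3.05 against -0.17, but on the authors' deposited ratio the list turned to the low side (-3.23 against -2.59). lncRNAs were high on both, with 2.01 here and 0.56 on the deposited ratio: the imprinted Airn was at 3.89, the small nucleolar RNA host Snhg3 at 3.08 and the imprinted Meg3 at 2.87, while Tug1 was at -1.72. Ribosomal protein (-3.04), astrocyte (-2.71), housekeeping (-2.54), Purkinje cell (-2.37), oxidative phosphorylation (-2.26) and inhibitory neuron (-1.77) lists were low. On the deposited ratio, however, housekeeping genes were high (-1.89), and ribosomal protein, astrocyte, Purkinje cell and oxidative phosphorylation lists were inside the random range. Others were outside on that ratio alone: granule neuron (-0.53), immediate early (-1.22) and imprinted genes (-1.88) high and endothelial markers (-3.93) low. Synaptic genes (-0.28) lay above lists of like expression (-1.25) but below lists of like span (0.24). In all, 9 of 19 lists lay outside the range of random lists matched on expression. Against the null, RNAs with more RIP reads had slightly higher changes (correlation 0.17 across 9422 genes). Given the gene span this was 0.16. The RIP ratio, a different measure, gave -0.27 when taken over the first wild type library and set against the change from the second, and 0.01 with the libraries exchanged, so the sign of this relation was not settled.

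**Figure D3:**
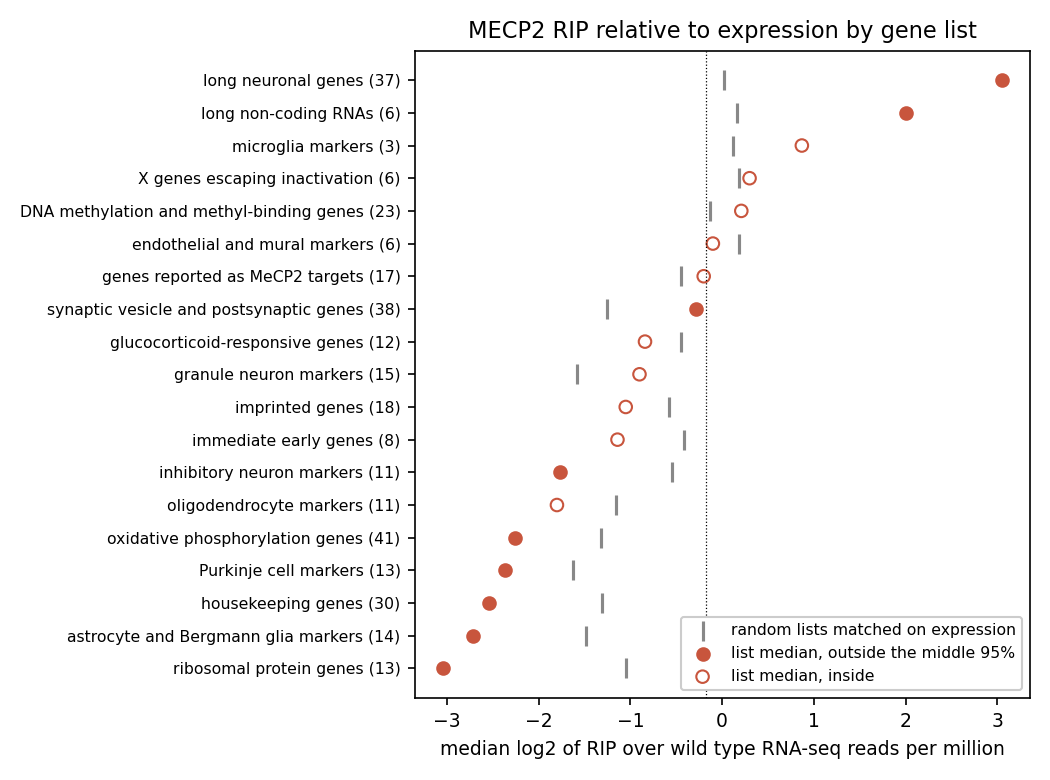
Median log2 of MECP2 RIP over wild type RNA-seq CPM for 19 gene lists (points) and for random lists matched on expression (bars), with the median gene as a dotted line at -0.17 and the number of genes in brackets. Long neuronal genes (3.05) and lncRNAs (2.01) lie highest and ribosomal protein genes (-3.04) lowest; on the authors' ratio per kb of span the long neuronal list lies on the low side and the housekeeping list on the high side.

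Among the lncRNAs recovered with MECP2, the nuclear speckle RNA malat1 and the imprinted meg3 were the most abundant, at 3740 ± 1260 and 2060 ± 130 CPM in males and 3450 ± 1560 and 1920 ± 151 in females (SD, n = 3 each). They were followed by zfhx2as (633 and 705 CPM in males and females), the imprinted antisense RNA air (504 and 590), rncr3 (387 and 452), the imprinted rian (330 and 348), and linc1582 (303 and 388). Lower levels were found for kcnq1ot1 (257 and 259), ipw (242 and 239), meg9 (92 and 125) and the paraspeckle RNA neat1 (73.1 and 69). In males snhg3 was at 64.6 ± 64.2 CPM, but at 27.6 without the third library. gomafu was at 50.9 ± 32.3, sox2ot at 38.4 ± 18.2, lxrbsv at 31.3 ± 10, tug1 at 27 ± 9.21 and antipeg11 at 26.1 ± 10.4. Without a control precipitation these levels cannot be set against background.

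The sex comparison asked which RNAs recovered with MECP2 differ between male and female cerebellum. There is no control precipitation, and the RNA-seq libraries give no comparison of the sexes. A difference in RIP reads between sexes therefore cannot be told apart from a difference in RNA level. The X inactivation RNA Xist (chromosome X, 100655714 to 100678556) was at 476 ± 76.6 CPM in females and 2.66 ± 1.42 in males (SD, n = 3 each; log2 7.34, SE 0.33, adjusted p = 1.56e-06). Its antisense partner Tsix (100626856 to 100680296) had nearly the same reads, 478 ± 76.4 and 3.32 ± 0.889 (6.98, SE 0.23, adjusted p = 1.25e-07); the spans overlap and the strand is not given, so which of them the reads come from is uncertain. The Y-linked Uty was higher in males, at 58.4 ± 12.9 against 3.44 ± 0.609 (log2 -3.89, SE 0.28, adjusted p = 0.000151), as was the Y-linked histone demethylase gene Kdm5d, at 30.6 ± 4.06 against 1.23 ± 0.672 (-4.25, SE 0.44, adjusted p = 0.00406). The fifth gene was autosomal: Nr4a3, an activity-induced nuclear receptor gene (chromosome 4, 48058025 to 48099319), at 76.8 ± 23.3 in males and 14.7 ± 2.45 in females (-2.31, SE 0.26, adjusted p = 0.00753). The lowest male library was at 50.6 and the highest female one at 17.5. Mecp2 RNA differed by -0.04 (SE 0.14, adjusted p = 0.959).

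Of the other Y-linked genes, Ddx3y had 83 male and 6 female reads (log2 -4.45, adjusted p = 0.112) and Eif2s3y 56 and 1 (ratio 0.0132, interval 0.000329 to 0.0768, adjusted p = 0.201). Too low to test were Usp9y with 12 male and 25 female reads, Zfy1 with 15 and 15, Zfy2 with 6 and 8, Ube1y1 with 0 and 3, and Sry with none in either (0 and 0). With limma 5 of 12921 genes passed, 2 higher in females and 3 in males, against 893 at an unadjusted p under 0.05. DESeq2 called 17 genes and edgeR 9, both including these 5. Kdm5d missed the threshold without the first male (adjusted p = 0.124) or the second (0.0604), and Nr4a3 without the second male (0.0604) or the second female (0.0638); 3 genes were left without the second male and 13 passed without the first female.

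**Figure D4:**
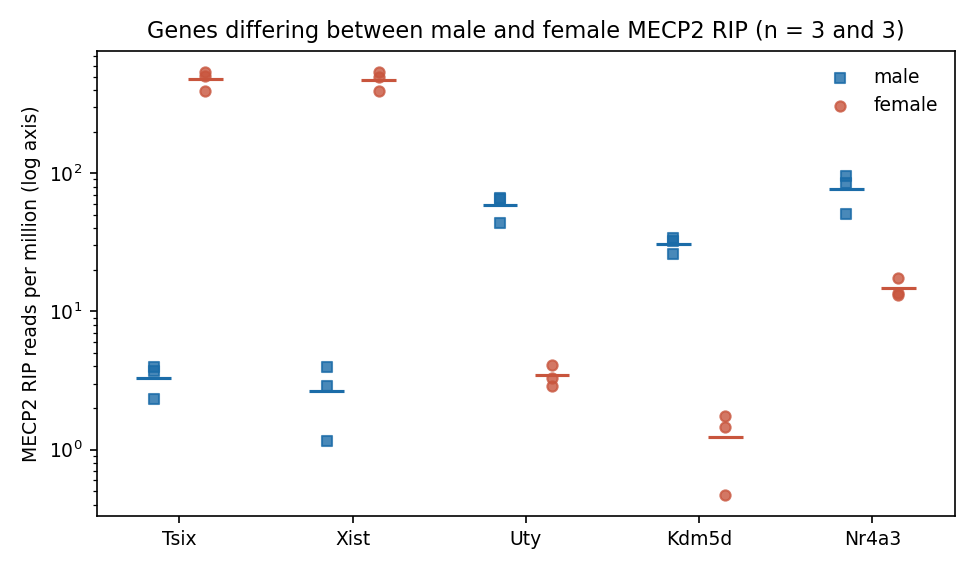
MECP2 RIP level in CPM (log axis) of the 5 genes that passed between sexes, 1 point per library and a bar at each mean (n = 3 male and 3 female). Tsix and Xist are higher in every female library, and Uty, Kdm5d and Nr4a3 in every male library.

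Of 30 lncRNAs tested, 3 passed, all higher in females and all from the Xist region: tsix (adjusted p = 3.85e-09), xist (1.53e-08) and the repa transcript, which lies inside Xist (431 reads against 2; ratio 160, interval 43.9 to 1322; limma adjusted p = 1.24e-07). gomafu, a nuclear RNA also called Miat, was at 50.9 ± 32.3 CPM in males and 14.6 ± 9.44 in females (SD, n = 3 each; log2 -1.76, limma adjusted p = 0.27). Without the third male library, the shallowest, 8 lncRNAs passed, with air (adjusted p = 0.0381), rncr3 (0.0421), linc1582 (0.000928) and meg9 (0.0103) added as higher in females and gomafu (1.83e-05) as higher in males. gomafu also passed without the first female (0.0438) and with a replicate block (0.00367), although the replicate numbers do not pair the libraries. DESeq2 called 4 lncRNAs, 3 higher in females and 1 higher in males.

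By gene list, Y-linked genes fell in females with a median log2 of -4.33 (camera adjusted p = 9.9e-15, and adjusted p = 0.028 with an estimated correlation). Of 4 members 2 passed adjusted over all genes, and 4 adjusted over the list alone. X genes escaping inactivation had a median of 0.37 (camera adjusted p = 3.36e-06), a call lost with an estimated correlation (adjusted p = 0.254). Of 9 members 2 passed over all genes (Xist and Tsix), and 4 adjusted over the list alone, with the demethylase genes Kdm6a (0.88) and Kdm5c (0.48) added. Immediate early genes stood at -0.64, lower in females (camera adjusted p = 1.19e-05), also lost with an estimated correlation (adjusted p = 0.319). Of their 13 members 1 passed over all genes, and 5 adjusted over the list alone: Nr4a3, Nr4a1 (50.1 CPM in males and 15.8 in females), Fos (20.8 and 5.41), Dusp1 (34.5 and 15.2) and Npas4 (11.6 and 3.74).

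Markers of glia and of blood stood in the same direction as the immediate early genes. Astrocyte markers had a median of -0.44 (camera adjusted p = 2.85e-05, and adjusted p = 0.628 with an estimated correlation), with the sodium pump gene Atp1a2 (-0.46) and the gap junction gene Gjb6 (-1.0) passing adjusted over the list alone and none (0 of 14) over all genes. Oligodendrocyte markers were at -0.21 (adjusted p = 0.00217, and adjusted p = 0.406 with an estimated correlation), oxidative phosphorylation genes at -0.17 (0.0126 and 0.713) and the 3 blood cell genes at -0.81 (0.0271 and 0.544), with 0 members past the threshold over all genes and 0 adjusted over the list alone in each. The blood list missed the threshold without the third male (adjusted p = 0.099), the first female (0.0872) or the third female (0.149). So did the oligodendrocyte list without the first female (0.0872), and the oxidative phosphorylation list without the first male (0.172), the second male (0.689) or the second female (0.0761). The other 17 of 24 lists did not pass; for the lncRNA list camera's direction was upward while its median was -0.10 (adjusted p = 0.0909).

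Region profiles asked whether MECP2 and methylation differ between promoters of genes activated and repressed in wild type, within classes of high or low CGAT4. Activated and repressed promoters held like amounts of MECP2: among 602 activated and 312 repressed promoters high in CGAT4, cerebellar mononucleosomes had a mean log2 of 0.15 ± 0.49 and 0.19 ± 0.52 (SD; difference -0.04, permutation p = 0.27, adjusted p = 0.5), and dinucleosomes 0.53 and 0.54. None of these 12 comparisons passed; the smallest adjusted p was 0.081, with 1 of them under 0.05 before adjustment. High CGAT4 promoters held more MECP2 than low ones in mononucleosomes of whole brain (difference 0.15, permutation adjusted p = 0.023) and dinucleosomes (0.09, adjusted p = 0.023) among activated genes. Cerebellar mononucleosomes (0.01, adjusted p = 0.86) and sonicated whole brain (-0.15, adjusted p = 0.081) did not pass there. Among repressed genes they held more in cerebellar mononucleosomes (0.11, adjusted p = 0.049), but less in sonicated whole brain (-0.24, adjusted p = 0.023). Dinucleosomes (0.1, adjusted p = 0.057) and mononucleosomes of whole brain (0.02, adjusted p = 0.86) did not pass among repressed genes. All these permutation p-values measure the spread between promoters within single libraries, not between samples. The classes are the authors' own calls of activation and repression, so the direction of the null change within them tests nothing. Many of these changes were small: against both wild type libraries, 143 activated and 140 repressed regions high in CGAT4 were within 1.2-fold, and 110 and 20 beyond 1.5-fold.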

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

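Of the tests in this part, the splits for lncRNAs and gene lists, the matching to nearest genes in span and both tests on ChIP and CG sites were chosen only after the result was seen.

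In mononucleosome ChIP, 4 gene lists stood on opposite sides of the median TSS in whole brain and cerebellum, each with 1 pair of libraries per tissue, and these differences were not tested. They are the lists with at least 10 genes, at least 0.1 from the median in both tissues, and outside the random range in at least 1. Astrocyte and Bergmann glia markers were at -0.18 in whole brain and 0.33 in cerebellum, a difference of 0.51 on the log2 scale. Microglia markers were at 0.28 and -0.16, a difference of -0.44. Glucocorticoid-responsive genes were at -0.71 and 0.13, a difference of 0.84. Housekeeping genes were at -0.13 and 0.39, a difference of 0.52. Another 5 lists were on opposite sides without meeting these limits. Against medians of -0.11 and 0.03 over all TSSs, they were granule neuron (-0.38 and 0.37), DNA methylation (-0.18 and 0.53), Purkinje cell (-0.45 and 0.10), reported MECP2 target (-0.20 and 0.21) and blood cell genes (0.38 and -0.29).

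The recovery of long neuronal genes such as Kcnip4 and Fgf14 with MECP2 was weighed against 2 technical sources. Genomic DNA in the RIP libraries is argued against: the 1307 olfactory and vomeronasal receptor genes, mostly silent in cerebellum, had at most 0.0309 of the reads per kb of expressed genes in any of the 6 libraries, below the bound of 0.1 set beforehand. Gene span alone, as unspliced RNA counted over introns would give, remains a candidate explanation: the list's median of 3.05 lay at percentile 94.6 of lists drawn from the 20 nearest genes in span (median 2.72, middle 95% from 2.17 to 3.22). The coarser 20-bin matching, run first, put the list at percentile 100, but its matched genes had a median span of 422 kb against 1098 kb in the list and 1094 kb among nearest genes, so it did not match these genes. Span does not reach the lncRNAs (2.01 against -0.31 at like spans) or ribosomal protein genes (-3.04 against -1.03), and whether MECP2 itself prefers long nascent RNAs stays open without a control precipitation; no biological explanation was tested.

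The opposite relations of sonicated and dinucleosome ChIP with the CG number were weighed against tissue and input. The bound coverage itself ran in opposite directions, with -0.38 in sonicated whole brain and 0.73 in cerebellar dinucleosomes. Both inputs ran in the same direction, with 0.21 and 0.67. In sonicated whole brain the bound coverage thus went against its input, which argues against input coverage as the whole cause there. In dinucleosomes the bound value lay close to that of the input, so it cannot decide the question. Tissue and preparation cannot be told apart. Mononucleosomes of whole brain had a correlation with the CG number of -0.03, not the -0.51 of sonicated whole brain, but this is 1 pair of libraries and its agreement with the other preparations was low (0.02 to 0.07). Between mononucleosome preparations tissue went with the trend, at -0.03 in whole brain and 0.25 in cerebellum. Fragmentation by sonication or nuclease differs too and may contribute, but no pair of libraries separates it from sample and sequencing run.

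The capture of dense methylation at promoters of expressed genes such as Rpl10a and Rps8 was weighed against reads shared with processed pseudogenes, copies that are often methylated. Of 260 expressed genes with a pseudogene named after them, 57 (21.9%) had at least 10 high density reads, against 3.99% of genes matched on expression and CG number (middle 95% from 1.92% to 6.54%), a ratio of 5.5. Without ribosomal protein genes the share was 15.5% against 3.96%. These values are consistent with shared reads as a source of the signal, though the deposited counts hold no mapping quality to settle it, and no biological explanation was tested.

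For the sex comparison of RIP, the 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 5 genes and the highest other split 46, so 2 of the splits gave at least 5. For lncRNAs the real split gave 3 and the highest other 0, so only 1 split, the real one, gave as many. For gene lists both the real split and the highest other gave 7, so 2 splits gave as many. The split with 46 genes set the first and second male and the first female apart from the rest. This points to a difference between libraries other than sex. Depth differed along this split, with 2387637, 1737722 and 3472601 reads in genes against 507104, 694670 and 2088638. Whether depth accounts for the 46 genes was not tested.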

How the results depend on the processing

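Among the alternatives, edgeR, the authors' fold changes, reads per kb of span, span matching, exchanged wild type libraries, correlations given the CG number, the list without Mecp2 and the sonicated preparation for expression were chosen only after the data were seen. Of 108 alternatives, 75 were labelled as leaving the result in place, 30 as moving it and 3 as reversing it. The causes were not tested unless said. For counts, in place means within 1.5 times the main count, whichever genes or lists were counted and in whichever direction. The authors' fold changes were thus labelled in place with 781 genes higher and 1520 lower, against 107 and 1585. So were the 8 null lists without matching, where oxidative phosphorylation and olfactory receptor lists replaced ribosomal protein and DNA methylation lists. Male against female RIP gave 17 genes with DESeq2, 9 without a filter, 9 with edgeR and 3 to 13 leaving out 1 library (3 without the second male, 13 without the first female), against 5. For lncRNAs it was 3 to 8 (8 without the third male) against 3, and for gene lists 6 to 10, and 1 with an estimated correlation, against 7. A replicate block gave 6 genes, 4 lncRNAs and 8 lists, although the numbers do not pair the libraries. Null against wild type gave 5946 genes without a filter, 596 at 5 RPKM and 469 at 2-fold, where the construction sets the count, 3 with edgeR, and 1273 to 2737 leaving out 1 wild type library (2737 without the first), where the lone null and lone wild type sample have no test, against 1692. ChIP gave 99 TSSs after centring against 198, and the agreement was 0.27 by Pearson correlation against 0.28. Methylation capture gave 647 TSSs at 50 reads against 1139. ChIP against methylation, 0.05, became -0.11 in dinucleosomes, 0.06 by Pearson correlation, 0.07 given input and 0.10 given the CG number. ChIP against expression, 0.22, became 0.48 in dinucleosomes, 0.26 given input, 0.07 given the CG number and -0.45 in sonicated whole brain. ChIP against the null change, 0.04, became 0.07 given input. Methylation against expression, -0.24, became -0.03 at 10 reads, -0.05 at 50 reads, -0.04 given low density reads and -0.16 given the CG number. RIP against expression, 0.56, became 0.48 at 5 RPKM and 50 reads, 0.57 in males, 0.53 in females and 0.54 to 0.56 leaving out 1 library. RIP against the null change, 0.17, became 0.14 at 5 RPKM and -0.27 with the RIP ratio in place of the level and with different wild type libraries for ratio and change, 2 changes at once. The planned change of preparation for methylation against expression was not run, since a single capture preparation exists. Depth limits the methylation capture, with a median of 3 reads per TSS.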

Other observations

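The regions with the highest ChIP coverage, singled out here after their values were seen, were 10 predicted gene entries in clusters on chromosomes 9 and 2, places known for reads from repeated sequence. MECP2 exceeded input there in all 4 preparations. At Gm10800 (chromosome 2, 98506458 to 98508458) log2 MECP2 over input was 0.47 in sonicated whole brain, 1.74 and 0.90 in mononucleosomes of whole brain and cerebellum, and 1.38 in dinucleosomes. At Gm10717 (chromosome 9, 3024417 to 3026417) the values were 0.47, 1.73, 1.02 and 1.39. Both had many MethylMiner reads, with 5079 high and 4863 low density reads at Gm10800 and 7316 and 6902 at Gm10717. Input coverage in cerebellar mononucleosomes was high there too, at 34400000 units for Gm10800 and 7915255 for Gm10717. The capture has no input library, so these counts cannot tell methylation from repeated sequence. Neither entry had RNA in wild type cerebellum (0 RPKM).

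Among captured TSSs outside these clusters, the highest counts were at small RNA entries on chromosome 17, with 3875 high and 670 low density reads at Mir715 (39980081 to 39982081) and 3350 and 722 at mmu-mir-2133-2.1. Next was Sfi1, a centrosome gene, with 1733 and 625. Dux, a repeated homeobox gene, had 464 and 159.

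The Y-linked genes gave a check on sample labels in the RNA-seq data: all 3 libraries held RNA of Uty, Ddx3y, Kdm5d and Eif2s3y, with log2 null changes of -0.75, -0.53, -0.45 and -0.42.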
